A study of Mus musculus with 4 samples.

How the data were processed

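Single-cell RNA libraries (10x 3′ v3 chemistry) and tag libraries prepared by a CITE-seq-type protocol were made from GFP-positive mouse keratinocytes of the MK line, per the labels' protocols. Samples were grouped by title into 4 groups of 1 library each. The RNA matrices hold whole-number UMI counts per gene and cell barcode, deposited without normalization and made with Cell Ranger 6.1.2, per the file headers, and mm10, per the submitters' processing notes. The gene annotation was not given in the sources used here. The tag matrices hold whole-number counts per tag and cell barcode, as deposited, with tag sequences in the tag names. The tool that counted tags, how the tag lists were built and whether these counts are UMIs or reads were not given in the sources used here, so intervals on tag shares are over cells. Counts in an entry named unmapped, 18.2% of MK and 10.1% of Diff_MK tag counts, were kept out of totals and calls.

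Cells were kept at 1000 or more genes and at most 15% mitochondrial counts, which removed 605 of 7780 MK and 657 of 7569 Diff_MK cell barcodes. The smallest deposited total was 500 UMIs. UMIs of the kept cells (115181759 and 103885150) were summed per library and scaled by the library total to CPM. Ratios of CPM carry exact conditional binomial intervals, and shares carry exact Clopper-Pearson intervals, at the 95% level. With 1 library per group no p-value was computed. Genes at 10 CPM or more in at least 1 library with a ratio of at least 2 or at most 0.5 were counted as a description of these libraries. Of 30 gene lists fixed before the data were examined, the median log2 ratio of members at 5 CPM or more in at least 1 library was taken where 3 or more members were measured, with a floor of 3 counts, an order-statistic interval over members (their range for 3 or 4 members) and a percentile among 10000 random lists matched on size and mean expression. The lists cover basal, spinous and granular keratinocytes, stress and simple keratins, junctions, lipid barrier, cell cycle, CDK inhibitors, p53, Notch, EMT, TGF-beta and YAP, inflammation, interferon, immediate early genes, heat shock, ER stress, hypoxia, cholesterol synthesis, NRF2 and markers of melanocytes, fibroblasts, immune, endothelial, erythroid, hair follicle and Merkel cells. For shares of cells with a UMI, cells were thinned to 7500 UMIs, which left out 337 MK and 635 Diff_MK cells.

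The named genes are the 12 with the highest and the 12 with the lowest CPM ratio after adding 10 counts, among genes at 50 CPM or more in at least 1 library and leaving out predicted, mitochondrial and ribosomal protein genes, the members of each list with the highest mean CPM or the largest log2 ratio, members of the 3 keratinocyte lists above a CPM minimum, and leading genes of clusters. Endou, Krt1, Slc2a1, Hk2 and Fos, named in the report, and Xist, the Y-linked genes and the chromosomes in the closing section lie outside this rule and were chosen after their values were seen.

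For clusters, counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were scaled, and 30 principal components gave exact 15-nearest-neighbour graphs whose edges were weighted by shared neighbours, a choice not written down before the data were examined. Leiden clustering ran at resolution 0.5 without integration. Clusters were named from markers fixed before the data were examined. Doublets were not removed, and leaving out the cells with the highest Scrublet scores (488 MK and 431 Diff_MK cells) was an alternative. Gene positions come from GENCODE vM21 on GRCm38, in which 32158 of 32285 genes (99.6%) were found by identifier.

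Cells were joined to tags by their 16-base cell barcode. A tag was called at 3 or more counts and at least 10% of a cell's tag counts. A clone is the set of cells whose leading tag had 3 or more counts and at least 2 times those of the next. Tags of the libraries were matched over the shorter of both lengths (93 pairs, of which 82 were identical). Clone numbers were also taken after drawing equal numbers of cells 1000 times. Similarity within clones was measured over clones of 5 or more cells, and composition over clones of 20 or more. After seeing the data, tags were also shuffled over the assigned cells of a library 100 times, and 20 cells were drawn from each clone 100 times. Comparisons of lists within tags used the ratio of summed list counts, not the median of members.

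The steps were tested on simulated data. For the comparison of the RNA libraries, over 7467 genes, 95.1% of intervals held the true ratio. Of 100 genes changed 3-fold, 100% were found at 2-fold or more, of 100 changed 1.5-fold 0%, and of unchanged genes 0%. Both simulated libraries were drawn from 1 shared profile with counting error only. The gene shares therefore say nothing of variation between libraries of the same group. Of 40 random lists shifted by 0.5, 97.5% lay above the 97.5th percentile, and 40 lists without a shift had a mean percentile of 42.9. Noise in these lists was independent for each gene, so members that vary together were not simulated. Of simulated cells, 99.3% were assigned a clone with MK tags and 95.8% with Diff_MK tags, of which 99.98% and 99.95% had the true tag. Every simulated cell carried a single true tag over a background drawn from the library's tag totals. Untagged cells, doublets and cells with several tags were not simulated, so these shares are not the accuracy of clones in the real cells.

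Alternatives were other cell filters, scaling by the median ratio of genes, equal weight per cell, other gene minima, Scrublet filtering, other tag minima, all deposited cell barcodes, no dominance condition, clones as identical sets of tags, cluster resolutions 0.3 and 1.0, separate clustering and removal of cell cycle genes. Full identity of tags was added after seeing the data. Chromosome medians used clones of 50 or more cells and genes at 50 CPM or more. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9. Sequencing reads were not used here, and 1 member of the basal list is not reported here.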

Results

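The series paired single-cell transcriptomes with heritable DNA tags in MK, a mouse keratinocyte line, the main cell type of the epidermis. Dox, the usual short form of doxycycline, an antibiotic that switches on inducible transgenes, is part of every sample's label, and cells carrying a tag were sorted by GFP fluorescence before droplet capture. The 4 samples form 4 groups of 1 library each, an RNA library and a matching tag library for the cells labelled MK, and the same pair for the cells labelled Diff_MK. The labels do not spell out what Diff stands for, so the groups are named as labelled. No replicates exist, so no test between groups was made, and every difference below is one between 2 RNA libraries or 2 tag libraries. The RNA files held 7780 cell barcodes and 116732898 UMIs for MK and 7569 cell barcodes and 105961628 UMIs for Diff_MK. After filtering, 7175 MK cells had a median of 15599 UMIs (range 1691 to 49306) and 3881 genes, and 6912 Diff_MK cells had a median of 14223.5 UMIs (range 1768 to 42875) and 3460.5 genes. The median mitochondrial share was 5.42% and 6.08%. Intervals of ratios and shares are exact 95% intervals and cover counting error only, while those of list medians describe the spread of list members.

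The first comparison asked how the transcriptome of the Diff_MK library differed from that of the MK library. The largest ratio belonged to Krt15, a type I keratin of basal and hair follicle stem cells, at 1.02 CPM in the MK library and 708 CPM in the Diff_MK library, a ratio of 691 (interval 577 to 835). Lgals7, which encodes the epithelial galectin-7, was 26.9-fold higher in the Diff_MK library, at 33.9 CPM and 914 CPM. The keratin gene Krt19 was 5.06-fold higher (251 and 1272 CPM) and Ly6d, a surface antigen of stratified epithelia, was 4.40-fold higher (279 and 1226 CPM). Among the 7736 genes at 10 CPM or more in at least 1 library, 141 were at least 2-fold higher and 60 at least 2-fold lower in the Diff_MK library. The median log2 ratio over 8765 genes at 5 CPM or more in both libraries was -0.15, and scaling by the median ratio of genes in place of total UMIs gave 192 genes higher and 30 lower. Weighting each cell equally gave 169 higher and 120 lower. With a minimum of only 10 counts in place of 10 CPM, which lets in low genes, the balance turned to 774 higher and 1104 lower of 15388.

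The 12 genes with the highest ratios also held Asprv1, a protease of the granular layer, at 4.91 and 51.2 CPM, and Bnip3, a hypoxia-induced mitophagy receptor, at 5.74 and 59.2 CPM. Clu, encoding the chaperone clusterin, was 9.20-fold higher in the Diff_MK library, the hypoxia-responsive Ndrg1 9.04-fold and the beta-defensin gene Defb1 8.80-fold. Gadd45g was 4.32-fold, Jun 4.06-fold and Igfbp2 3.92-fold higher. At the other end, Lcn2, encoding the siderophore-binding protein lipocalin-2, had 51.3 CPM in the MK library and 6.94 CPM in the Diff_MK library and was 7.39-fold lower in the latter. The neutrophil chemokine genes Cxcl3 (3.76-fold) and Ppbp (3.25-fold) were lower in the Diff_MK library, as was Hmga2, an architectural chromatin protein gene, at 477 and 170.4 CPM. Lor, encoding the cornified envelope protein loricrin, was 2.74-fold lower, at 83.8 and 30.6 CPM. Timp1, Taf4b, Arhgdib, Ppfibp1, Tnnt2, Nop56 and Samhd1 completed these 12, between 2.06-fold and 2.54-fold lower.

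Shares of cells with a UMI were compared for 3 of these genes. With every cell thinned to 7500 UMIs, Krt15 was detected in 0.658% of MK cells (interval 0.480 to 0.880%) and 41.9% of Diff_MK cells (40.7 to 43.2%), against 1.20% and 52.97% without thinning. Lgals7 was detected in 14.6% and 61.9% of thinned cells, and in 22.4% and 73.4% without thinning. Lor went the other way, with 16.7% and 8.16% of thinned cells and 25.5% and 13.2% of all cells. No cell type lacking these genes was present to measure free RNA, and the low Krt15 share of the MK library was not separated from it. On GRCm38, Krt15 (ENSMUSG00000054146) spans chromosome 11, 100131758 to 100135928, minus strand, and Krt14 (ENSMUSG00000045545) lies on the same chromosome at 100203162 to 100207548. Lgals7 (ENSMUSG00000053522) spans chromosome 7, 28863853 to 28866284, plus strand, and Lor (ENSMUSG00000043165) chromosome 3, 92080271 to 92083142, minus strand.

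**Figure D1:**
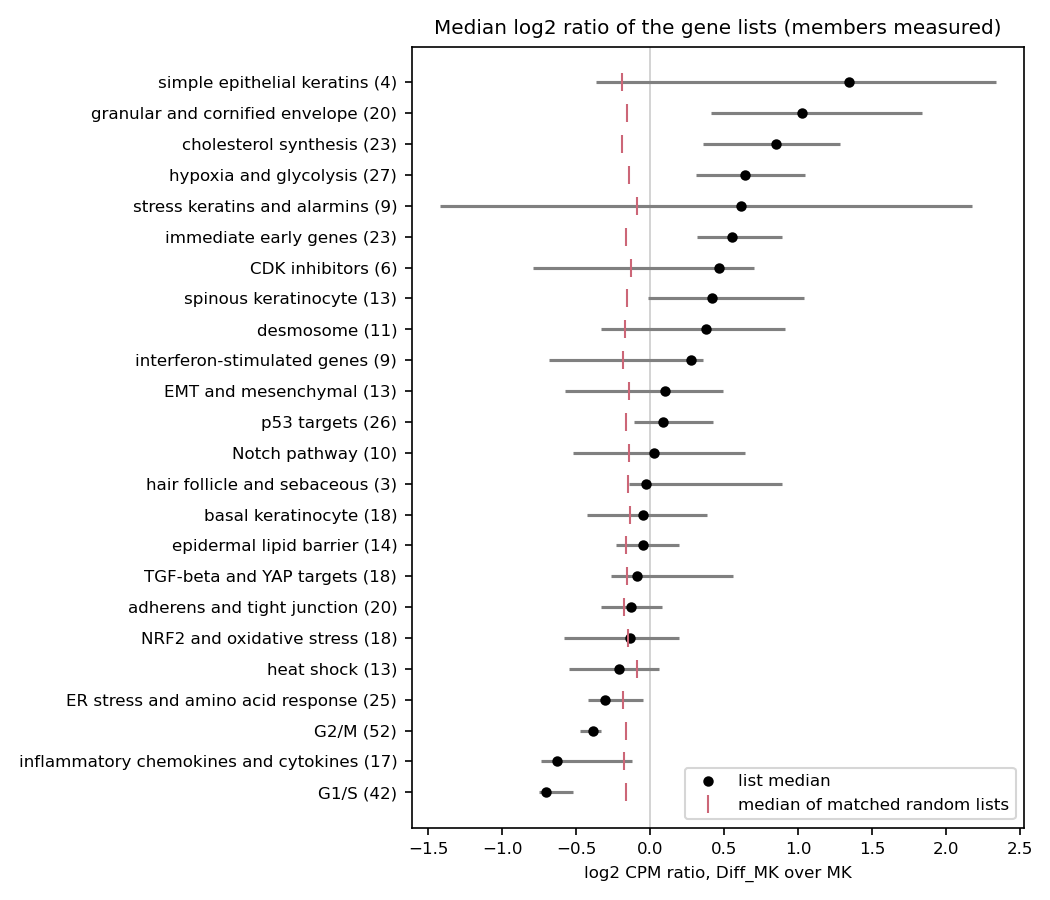
Median log2 ratio (Diff_MK over MK) of each gene list with 3 or more measured members, with points for list medians, horizontal lines for 95% order-statistic intervals over members (for the lists of 3 and 4 members the range of members, which covers less than 95%) and red ticks for the median of expression-matched random lists. The granular and cornified envelope list lies at 1.02, the cholesterol synthesis list at 0.85 and the G1/S list at -0.71.

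Gene lists for stages of epidermal differentiation were fixed before the data were examined, and differences between lists were not tested. The granular and cornified envelope list, genes of the outer living layers, had a median log2 ratio of 1.02 (order-statistic interval 0.41 to 1.84), with 17 of 20 measured members higher in the Diff_MK library, 10 of them at least 2-fold. Sprr1b had 513 and 1191 CPM, Spink5 401 and 912 CPM, Cdsn 9.57 and 34.2 CPM, and involucrin (Ivl) 43.3 and 75.2 CPM. Lor, Tchh and Sprr2e were its 3 lower members. Its largest ratios were those of Lce3c (0.0521 and 9.33 CPM) and Crct1 (0.564 and 26.1 CPM). Crct1 averaged 4592 CPM in the 47 cells of cluster 13, described below, and 4.13 CPM in all other cells. With cells at 2000 or more genes and at most 10% mitochondrial counts, the list median was 0.80 over 19 members. The spinous list had a median of 0.42 (-0.01 to 1.04) with 10 of 13 members higher. Its members with ratios of at least 2 were Lgals7, Ly6d and Endou, while Krt10 stood at 27.0 and 29.1 CPM and Krt1 had fewer than 5 CPM in both libraries. Both medians lay above those of 100% of 10000 random lists matched on size and expression. The Sprr, Lce and Krt6 genes belong to families of near-identical copies, and how the authors' counting divided their reads was not tested.

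The basal list had 8 of 18 measured members higher and a median of -0.05 (-0.43 to 0.39), above 86.5% of random lists, and its sign turned positive under median scaling. Its summed CPM, most of it Krt14 and Krt5, had a ratio of 1.90, against 1.99 for the spinous and 2.04 for the granular list. Krt14 had 6295 and 12790 CPM (2.03-fold higher in the Diff_MK library), and Krt5 (ENSMUSG00000061527, chromosome 15, 101707070 to 101712898) had 1152 and 3140 CPM (2.73-fold higher). The integrin genes Itgb1, at 520 and 334 CPM, and Itga3, at 191 and 145 CPM, were lower. Trp63, the master regulator of stratified epithelium, stood at 88.9 and 86.4 CPM. The simple epithelial keratin list had a median of 1.34 with 3 of 4 members higher, Krt8 being the exception at 93.0 and 72.3 CPM. Stress keratins and alarmins had a median of 0.61 but an interval from -1.42 to 2.17, with 5 of 9 members higher (Krt6a 1783 and 3129 CPM) and 4 lower (Slpi 626 and 376 CPM). The desmosome list, genes of cell-cell anchoring junctions, had a median of 0.38 with 8 of 11 members higher, including Dsp (330 and 627 CPM) and Perp (519 and 871 CPM). The adherens and tight junction list (-0.13) and the epidermal lipid barrier list (-0.05) changed sign under median scaling, with 7 of 20 and 6 of 14 members higher.

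Cell cycle genes were lower in the Diff_MK library. All 42 G1/S genes had a lower CPM there, with a median log2 ratio of -0.71 (-0.75 to -0.52). Pcna, the DNA polymerase clamp, had 246 and 130.4 CPM, and the ribonucleotide reductase subunit gene Rrm2 had 272 and 160.3 CPM. Of 52 G2/M genes, 49 were lower, with a median of -0.39 (-0.47 to -0.33), below those of all random lists (percentile 0 for both). Under median scaling the G2/M median was -0.23. Of 6 CDK inhibitor genes, 5 were higher and Cdkn2c was lower, with a median of 0.46. Cdkn1a, encoding p21, had 176 and 237 CPM. The p53 target list had a median of 0.09 (0.24 under median scaling) with 16 of 26 members higher. The Notch list had a median of 0.03 that turned negative without the cells of highest doublet score, and its receptor gene Notch1 had 33.1 and 73.6 CPM.

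Most members of the cholesterol synthesis, hypoxia and glycolysis, and immediate early lists were higher in the Diff_MK library. All 23 cholesterol synthesis genes were higher in the Diff_MK library, 10 of them at least 2-fold, with a median of 0.85 (0.36 to 1.28). Fdps, the farnesyl diphosphate synthase gene, had 123 and 344 CPM, and Mvd 16.6 and 52.6 CPM. Of 27 hypoxia and glycolysis genes, 26 were higher, with a median of 0.64 (0.31 to 1.05). The glucose transporter gene Slc2a1 had 90.4 and 231 CPM, while the abundant Gapdh stood at 5706 and 5840 CPM and Hk2 was the lower member at 44.7 and 36.9 CPM. Immediate early genes had a median of 0.56 (0.32 to 0.89) with 19 of 23 members higher, among them Fos at 99.7 and 368 CPM. These 3 medians lay above 100% of random lists.

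Inflammatory chemokine and cytokine genes had a median of -0.63 (-0.74 to -0.13), with 13 of 17 members lower and a percentile of 0. Cxcl5 had 1515 and 908 CPM, and the monocyte chemoattractant gene Ccl2 had 10.7 and 1.21 CPM. Interferon-stimulated genes had a median of 0.27 (0.43 under median scaling) with 5 of 9 members higher, but their summed CPM ratio was 0.824, since the abundant H2-D1 had 396 and 240.3 CPM. ER stress and amino acid response genes had a median of -0.30 with 20 of 25 members lower, and heat shock genes a median of -0.21 with 9 of 13 lower, Hspb1 (1828 and 3072 CPM) and Hspd1 (1366 and 804.5 CPM) lying on opposite sides. Matched random lists had medians of -0.19 and -0.09, which placed ER stress at percentile 3.89 and heat shock at 9.67. Under median scaling the ER stress median was -0.15 and the heat shock median -0.06. The EMT and mesenchymal list had a median of 0.10 (0.25 under median scaling). The TGF-beta and YAP target list (-0.09), the NRF2 and oxidative stress list (-0.14) and the hair follicle and sebaceous list (-0.03) changed sign under median scaling. Of the markers of other cell types in skin, 0 melanocyte, 0 fibroblast, 0 endothelial and 0 erythroid genes reached 5 CPM in either library. The immune list had 1 such gene, Cd68 (6.25 and 5.20 CPM), and the Merkel cell list had 1, Sox2 (13.2 and 6.93 CPM).

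Clustering of both RNA libraries together asked which states the cells occupied. It gave 14 clusters, and 53.6% of cells lay in clusters of which at least 90% came from 1 library, so a cluster may stand for a library as much as for a state and cluster sizes are not compared. Cluster 1, led by Hist1h1b, Hist1h2ae and Mcm5, was S phase-like, with all 10 fixed markers at least 1.5-fold above the other cells, and cluster 5, led by Cenpf, Nusap1 and Aspm, was G2/M phase-like, also with 10 of 10. Cluster 13, 47 cells led by Crct1, Calm4 and Sprr1a among others, was granular keratinocyte-like with 6 of 8 detected markers, and the prolactin-family genes Prl2a1 and Prl7b1 were also among its leading genes. Cluster 2 held 1844 Diff_MK and 0 MK cells, was led by Krt15, Clu, Lgals7 and Ndrg1, and had few cell cycle transcripts, with S phase and G2/M phase markers at median log2 ratios of -3.10 and -4.24 to all other cells. Cluster 7, with 1108 Diff_MK cells and 1 MK cell, had Elovl6 and the cholesterol synthesis genes Idi1 and Acat2 among its 5 leading genes, and cluster 10, with 501 Diff_MK and 0 MK cells, had Krt6b, Krt78 and Asprv1. Cells of both libraries met in cluster 3, led by Krt16, Fxyd2 and Krt17 (40.6% Diff_MK cells), and in cluster 8, led by Lor, Lcn2 and Tchh (36.6% Diff_MK cells). Cluster 12 held 58 cells with a median of 3654 UMIs and 0.0880% mitochondrial counts and stayed unnamed.

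The tag libraries addressed which cells shared a tag and so, under the design, a common ancestor. The start of the fixed left flank of the tags, AAAGGTCTAGAGCTAGCTGTGCCTGCTGGG, was found in 0 of 141767 mouse transcripts. The shortest tags, of 26 bases in MK and 25 in Diff_MK, are shorter than this sequence and cannot hold it in full. The MK tag library listed 1055 tags over 6411 cells and 3811098 counts, and the Diff_MK tag library 154 tags over 6454 cells and 4034391 counts. Tag counts per cell were similar, with medians of 354 and 381. They were spread over many tags, with a median of 140 tags per cell in MK and 58 in Diff_MK. The leading tag held a median of 35.3% and 33.3% of a cell's tag counts, at 10.6 and 4.60 times the next. A tag was called in 68.2% of MK cells (4893 of 7175, interval 67.1 to 69.3%) and 87.2% of Diff_MK cells (6027 of 6912, 86.4 to 88.0%). The size of this gap depended on the rule. A minimum of 10 counts gave 64.3% and 75.5%, and a leading tag at least 2 times the next was found in 63.6% and 68.7%. Of kept RNA cells, 764 in MK and 458 in Diff_MK had no entry in the tag matrix, with median UMIs of 20896 and 9073.5 against 15477 and 14424.5 in the cells that had one. More than 1 tag was called in 7.30% (6.58 to 8.06%) of tagged MK cells and in 23.1% (22.0 to 24.1%) of tagged Diff_MK cells.

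Assigned cells of the Diff_MK library fell into fewer clones. A dominant tag assigned 4560 MK cells to 898 clones and 4747 Diff_MK cells to 128 clones, or 127.1 on average when 4560 cells were drawn. The effective number of clones was 98.8 and 23.4. Clones of 1 cell numbered 408 in MK and 22 in Diff_MK, and clones of 20 or more cells held 2279 and 4379 of the assigned cells. The 10 largest clones held 23.2% and 53.6%. The largest clone held 280 MK cells (6.14%, interval 5.46 to 6.88%) and 539 Diff_MK cells (11.4%, 10.5 to 12.3%), and carried the same tag in both, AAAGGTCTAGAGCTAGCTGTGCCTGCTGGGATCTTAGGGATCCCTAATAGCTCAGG. That tag has no bases between its fixed flanks, and whether it arose more than once, in unrelated cells, was not settled. Clones defined as identical sets of called tags numbered 1202 in MK and 488 in Diff_MK, with 5.35% and 8.73% of cells in the largest. Without the dominance condition the largest clone held 10.7% of MK and 10.5% of Diff_MK cells, so its order depended on that condition. Clone numbers are bounded by the authors' lists, which held 1055 and 154 tags.

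**Figure D2:**
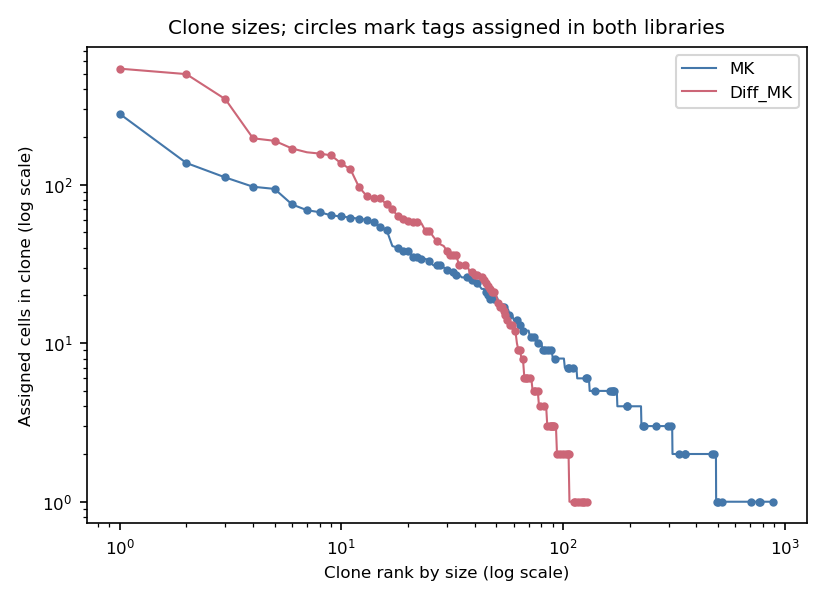
Assigned cells per clone against the rank of the clone by size, both on log scales, for the MK and Diff_MK libraries, with circles on clones whose tag was assigned in both libraries. The lines run from 280 cells over 898 clones in MK and from 539 cells over 128 clones in Diff_MK.

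Tags were shared between the libraries. Cells with a tag assigned in both made up 49.3% of assigned MK cells (47.9 to 50.8%) and 87.2% of assigned Diff_MK cells (86.3 to 88.2%), in 80 clones. Matching tags only when identical in full, chosen after seeing the data, gave 37.8% and 59.9%. Among tags whose junction could be read, 18 of 80 shared and 71 of 755 other MK tags had no bases between their fixed flanks, as did 17 of 78 shared and 4 of 40 other Diff_MK tags, and these shares were not tested against each other.

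Whether cells of a clone were more alike than cells of different clones was measured on thinned counts. In MK, the mean correlation was 0.696 within and 0.694 between clones, a difference of 0.00265 (SD 0.0123 over 165 clones) that was positive in 96 clones. In Diff_MK it was 0.673 and 0.656, a difference of 0.0170 (SD 0.0127 over 75 clones) that was positive in 71 clones. Of 46 MK clones of 20 or more cells, 16 had a share of some cluster whose interval lay apart from that of the other assigned cells (27 of 506 pairs of clone and cluster), and of 50 Diff_MK clones 43 did (128 of 700 pairs). In 100 shuffles of the tags over the same cells, added after the result was seen, at most 11 pairs in MK and 13 in Diff_MK did. Diff_MK clones were larger, which narrows their intervals, and with 20 cells drawn from each clone, also added afterwards, the mean number of such clones was 9.01 in MK and 30.9 in Diff_MK.

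The named genes were then compared within the 21 tags that had 20 or more cells in both libraries. Genes named for their library ratio were chosen on counts that include those of these tags, so their signs within tags are no separate evidence. Krt15, Lgals7, Krt19, Ly6d, Krt14 and Krt5 were higher in the Diff_MK library in all 21. Hmga2, Timp1, Taf4b, Tnnt2 and Nop56 were lower in all 21, Cxcl3 and Ppbp were higher in 1, Lor was higher in 4, and Lcn2 was higher in 6. The summed counts of the basal, spinous, granular, simple keratin, desmosome, cholesterol synthesis, hypoxia and immediate early lists were higher in 21 of 21 tags, those of the G1/S list lower in 21, of the inflammatory list lower in 20 and of the G2/M list lower in 19. The CDK inhibitor and p53 lists were higher in 20 and the stress keratin list in 19. The ER stress list was lower in 20 and the NRF2 list in 19. The remaining lists were higher in between 5 (adherens and tight junction) and 16 (Notch) tags. The median log2 ratio of the summed counts was 0.87 for the basal, 0.77 for the spinous and 1.01 for the granular list. Tags of 1 library are not replicates of the condition, and whether the same tag marks the same lineage in both libraries was not settled.

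**Figure D3:**
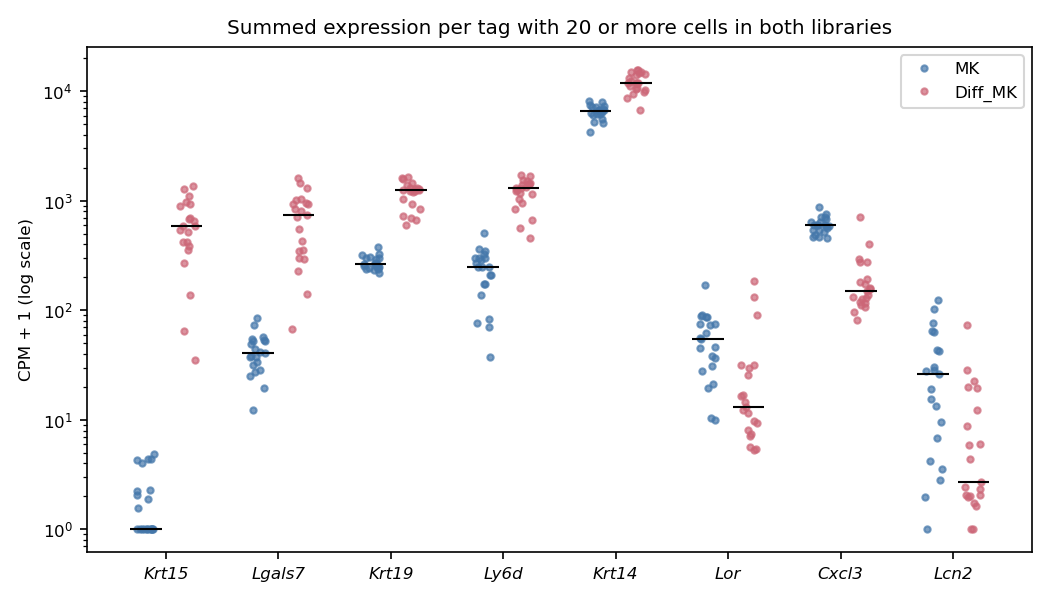
Summed expression of 8 genes in each of the 21 tags with 20 or more cells in both libraries, as CPM plus 1 on a log scale, with 1 point per tag and library and black bars at medians. Krt15, Lgals7, Krt19, Ly6d and Krt14 are higher in the Diff_MK library in all 21 tags, while Lcn2 is higher in 6.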

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

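The comparison of randomly split tags within a library and the Krt15 test within shared tags were chosen after the result was seen, and the other tests here before. Counts outside the listed tags were a signal in data that no comparison used, at 18.2% of tag counts in MK and 10.1% in Diff_MK.

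The same tags were found in both libraries, in 49.3% of assigned MK cells and 87.2% of assigned Diff_MK cells. Counts carried over from one library to the other after capture would keep their cell barcode, but only 3 cell barcodes were assigned a tag in both libraries and 0% of the 2250 MK cells with a shared tag had the same tag at the same cell barcode in Diff_MK (exact upper limit 0.164%), which argues against this route and not against mixing before capture. Profiles of the same tag in the 2 libraries correlated only 0.0281 more than profiles of different tags (0.0268 and -0.00126 over 21 tags), and 3 of 21 tags matched their own tag best. That value met the bound of 0.05 set beforehand for tags that arose independently and against lineages shared before the cultures parted, but the bound was wrong, because within MK, with each tag's cells split at random, the same tag exceeded different tags by only 0.0453 (0.0241 to 0.0629 over 20 splits), against 0.482 within Diff_MK, so the test had little to find. Independent origin and shared ancestry therefore cannot be told apart.

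The Diff_MK library had lower G1/S and higher hypoxia, cholesterol synthesis and Krt15 expression, and a different lineage makeup of the libraries could produce such differences. Within the 21 shared tags the median log2 ratio of summed list counts was -0.63 for G1/S (library sum -0.64) and 0.28 for hypoxia and glycolysis (0.27). For cholesterol synthesis it was 0.90 (0.92). Sums weigh abundant members more than the medians over members given earlier, such as 0.64 for hypoxia and glycolysis. For Krt15 the median over tags was at least 7.39 (library 9.43). Krt15 had 0 counts in 11 of the 21 MK tags and was set against a floor of 3 counts per tag. Each of the within-tag ratios had the library's sign in 21 of 21 tags. These values met the bounds against makeup, set beforehand except for Krt15, but those bounds take the same tag to mark the same lineage, which the 0.0281 above leaves open, so makeup and a difference within lineages cannot be told apart. The culture difference behind the label Diff remains an open biological explanation that the design, with 1 library per group, did not allow to be tested.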

How the results depend on the processing

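Among the alternatives, matching tags only when identical in full was chosen after seeing the data, and the others before the data were examined. Of 216 values under an alternative, 186 stayed within 1.5 times (counts), the interval (shares and medians) or 1 SD (correlations), 30 moved and 0 reversed as called values, and the cause was not tested except where the setting itself fixes it. Clone numbers, clone shares and correlations could not move under all deposited cell barcodes, because every cell of the tag matrices had been kept. The SD allowed for the MK correlation (0.0123) exceeded the MK difference itself (0.00265), so that bound was wide. Of 144 list medians 139 stayed within their interval, and 7, in 7 of 24 lists whose intervals held 0, took the other sign. Genes lower in Diff_MK numbered 30 under median scaling, 120 with equal weight per cell and 1104 (774 higher) with a minimum of 10 counts. The G2/M median was -0.23 under median scaling and -0.55 with equal weight, which also gave -0.87 for G1/S and -0.75 for inflammatory genes, and interferon genes stood at 0.43 under median scaling. A minimum of 1 count gave tagged shares of 70.2% (MK) and 92.9% (Diff_MK), with more than 1 tag in 8.80% and 30.6%. A minimum of 10 counts gave 64.3% and 75.5% tagged, 15.7% of Diff_MK with more than 1 tag and 4.77% in the largest MK clone. All deposited cell barcodes gave 62.9% and 79.6% tagged. Without the dominance condition the largest MK clone held 10.7%, and shared tags 56.1% and 88.8%. Clones as identical sets of tags gave 5.35% (MK) and 8.73% (Diff_MK) in the largest, 46.5% and 71.1% shared, and 488 Diff_MK clones. Full identity gave 37.8% and 59.9% shared. Resolution 1.0 gave 22 clusters. Depth limits low genes, such as Krt15 in MK. No paired analysis was possible because each group holds 1 library and no test was made.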

Other observations

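The share of cells with Y-linked genes and the spread under shuffled tags were tested after the result was seen, and the chromosome, Xist and clone patterns themselves were noticed in the data, while the other tests here were chosen before their values were seen. Clones of the Diff_MK library differed in 5 genes by more than shuffled tags did. The 5 genes were chosen after their shares over clones were seen, so passing the shuffles owes in part to that choice. Ly6d and Lcn2 were also looked at over clones but not shuffled. With cells thinned to 7500 UMIs, the SD over 47 clones of the share of cells with a UMI was 13.5 percentage points for Krt15, 19.6 for Lgals7, 13.9 for Lor, 17.2 for Krt8 and 17.5 for Tmem176b. The highest SD in 100 shuffles of the tags over the same cells was 9.45, 9.46, 5.35, 7.05 and 9.21. Over 46 MK clones the SDs were 0.922, 6.35, 6.73, 5.63 and 9.29, each under the highest of the shuffles (2.16, 7.69, 8.16, 8.24 and 10.0). Krt15, found in 0.658% of thinned MK cells, had little room to vary there. The clone Tag21 of Diff_MK, with 31 cells, had, without thinning, Lor in 77.4% (58.9 to 90.4%) and Krt8 in 77.4% of its cells, against 13.4% and 18.3% of the other assigned cells.

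Xist, the long noncoding RNA that coats the inactive X chromosome (X, 103460366 to 103483254, minus strand, GRCm38), was found in 96% (90.9 to 98.7%) of the 125 cells of the Diff_MK clone Tag14 and in 0.541% of the other assigned cells, at 335 and 0.884 CPM. Droplets with 2 cells are argued against by a median UMI count only 1.14 times that of the other assigned cells, and cells of another line without a Y chromosome by Y-linked genes in 72% of its cells (61.6% of the others). For silencing of the whole of an only X, the X-linked expression ratio was 0.891 (0.824 to 0.933). That lay above the 0.75 set as the upper bound of such silencing but short of the 0.9 set against it. By these bounds the question was not decided. Silencing of part of the X may fit and was not tested. An additional X chromosome was not tested either. Alone it would not bring the X-linked ratio below equal expression if the other assigned cells have the same active X dosage, which was not measured.

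Other Diff_MK clones nearly lacked Y-linked RNA. Any of Eif2s3y, Ddx3y, Kdm5d and Uty was found in 4.92% of the 61 cells of Tag17 and 3.23% of the 31 cells of Tag21, against 62.7% and 62.3% of the other assigned cells, at 0.998 and 1.19 times their median UMIs. Among MK clones low shares were common, with a median of 24.1% (range 0% to 70.8%, 5 of 46 clones under 10%), against a median of 63.9% over the Diff_MK clones (2 of 50 under 10%).

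Chromosome medians also differed between Diff_MK clones. In 38 of 500 pairs of clone and chromosome, in 21 of 25 clones, the interval of the median log2 ratio to the other assigned cells lay beyond 0.1, and in MK in 0 of 320 pairs over 16 clones. Tag17 had median ratios of 0.79 on chromosome 12, 0.80 on chromosome 15 and 1.19 on chromosome 6. A candidate explanation is chromosome copy number that differs between clones, against a few co-regulated genes. The medians of the parts of each chromosome on either side of its middle gene correlated at 0.35 over Diff_MK clones and chromosomes (0.56 in MK), between the bounds of 0.2 and 0.6 set beforehand, so these cannot be told apart.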
